A study of Mus musculus with 12 samples.

How the data were processed

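RNA sequencing libraries of C18-4 cells fall into 4 groups of 3 libraries, named 5NC, 8276OV, 3NC and 8276KD in the labels. The deposited table holds a signal per gene and library to 2 decimals, which the authors scaled for gene length and sequencing depth. Its header does not name the unit, and FPKM and TPM could not be told apart from the values. The labels give mm10 as the genome build. The aligner, the counting tool and the gene annotation are not given in the sources used here.

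The table has 17576 genes, of which 17458 matched the RefSeq annotation of the same assembly by gene ID, 17259 of them protein-coding and 83 lncRNA genes. Of 21900 protein-coding genes in RefSeq, 4641 had no row, so the gene set is incomplete, and counts of genes refer to this table alone. Mitochondrially encoded genes had no row, and 589 genes were at 0 in all libraries. A spreadsheet had turned 25 symbols into dates, and these were restored from the gene IDs. No row could be matched to lncRNA8276 by symbol or ID, so its own level was not analysed here.

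Read totals are not part of the table. In short genes with low values, 60.4% to 67.9% of the values lay within 0.15 read of a whole number of reads for the best spacing, against 30% by chance. This spacing put 14.4 to 16.2 reads per kilobase behind a value of 1, and the libraries at 88.5% to 100% of the deepest. The estimate assumed an effective length of the transcript less 150 bases. The variance between replicates was 1.3 to 6.27 times the counting variance this depth implies.

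Genes with a mean of at least 1 over the 12 libraries were tested, 11133 in all. Log2 of the value plus 1 was fitted with limma-trend (limma 3.58.1, R 4.3.3) as 4 group means in a single model. The contrasts were 8276OV minus 5NC, 8276KD minus 3NC, 5NC minus 3NC, and the overexpression effect minus the knockdown effect. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested in a contrast, with a threshold of 0.05. The pairing of controls and treatments was taken from their order in the design text, which does not state it outright, so each treated group was also set against the other control and against both pooled. Replicates are not stated to be separate cultures or infections, so the p-values measure only the spread between these libraries. Replicate numbers did not pair libraries of a treated group with those of its control, and no block was used in the model. Between the 2 treated groups, deviations from the group mean correlated across genes at 0.48, 0.60 and 0.02 for replicates 1, 2 and 3. Between the controls these correlations were 0.07, 0.11 and 0.06. Why replicates 1 and 2 of the treated groups varied together was not tested.

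Sets of genes were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, adjusted over the lists in each contrast. For lists, passing refers to camera, at the preset correlation unless stated. Fry makes no comparison with other genes and also passed lists that camera did not. Its adjusted p for the spermatogonial list was 0.00015 with overexpression and 0.0047 with knockdown, but 0.24 for the matrix list with knockdown. A list's mean difference is the mean log2 change of its members minus that of the other tested genes. The 22 lists were undifferentiated spermatogonia and self-renewal, differentiating spermatogonia and meiosis, post-meiotic germ cells, cell-cell adhesion, extracellular matrix and integrins, GDNF and FGF to MAPK signalling and targets, cell cycle and DNA replication, Wnt pathway, interferon response, NF-kB and inflammatory genes, p53 targets, integrated stress response and unfolded protein response, sterol synthesis and uptake, hypoxia and glycolysis, cytosolic ribosomal proteins, oxidative phosphorylation, mitochondrially encoded transcripts, replication-dependent histones, and markers of Sertoli cells, Leydig cells, peritubular myoid cells and fibroblasts, and macrophages. Lists with under 3 tested members were given no test.

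Named genes followed a rule. For each treated group it took the 6 genes with the largest rise and the 6 with the largest fall past the threshold, with libraries of the 2 groups not overlapping and a higher group mean of at least 3. For each list it took up to 3 members with the smallest p, of which most of those of the lists that passed, of the spermatogonial list and of cell adhesion are named. It also took the 6 genes called in opposite directions by the 2 treatments whose smaller change was largest. The grouping, contrasts, tests, lists, rule and most alternatives were fixed before the data were examined. The correction for GC content and length was added after seeing the data.

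Alternatives were a pseudocount of 0.1 in place of 1, no filter beyond a value above 0, a mean of at least 5, median-of-ratios rescaling, quantile normalization, no mean-variance trend, a replicate block, each library left out in turn, a change of at least 2-fold as well, only the 2 groups compared, the other control group, both control groups pooled, and a loess correction of each library on GC content and transcript length with a span of 0.5. GC content and length came from the GENCODE transcripts, and 98.8% of the tested genes had a value. The method was tested on simulated data with known changes in 11133 genes, 50 genes for each size. In the overexpression contrast it recovered 40% of changes of 1.2-fold and 90% of 1.5-fold, and in the knockdown contrast 42% and 96%, with 7.8% and 4% false calls. Between the controls it recovered 38% and 90%, with 10.1% false calls, and for the difference between the effects 16% and 78%, with 5.9%. Far fewer genes changed in the simulated data than were called in the real contrasts, so the adjusted threshold was stricter and these shares do not carry over directly. Transcripts of the named genes were compared with all GENCODE transcripts by blastn 2.17.0, and genes with over 95% identity across at least 50% of the transcript were treated as sharing sequence. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Analyses planned for read counts were left out, since the table holds scaled values.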

Results

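Gene expression was profiled by RNA sequencing in C18-4 cells, an immortalised line of mouse type A spermatogonia, in which a virus had been used to raise or lower lncRNA8276, a long non-coding RNA. The 12 libraries formed 4 groups of 3, overexpression (8276OV) with its control 5NC and knockdown (8276KD) with its control 3NC. Values are the authors' length- and depth-scaled expression values, written as mean ± SD with n = 3 libraries throughout. They summed to between 533099 and 561940 per library, with 14407 to 14658 genes above 0. From the spacing of low values, the libraries were estimated at 88.5% to 100% of the depth of the deepest, with 14.4 to 16.2 reads per kilobase behind a value of 1.

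Several genes linked to spermatogonial stem cells were well expressed in all groups, among them the laminin receptor subunit Itgb1, with a mean of 306 over the 12 libraries, the deubiquitinase Uchl1 with 92.9 and the tetraspanin Cd9 with 83.5. The GDNF receptor gene Gfra1 averaged 0.0992, the transcription factor gene Zbtb16 0.0233, and the germ cell RNA-binding protein genes Ddx4 and Dazl 0.0158 and 0.00917. Of 34 genes in the list for undifferentiated spermatogonia, 31 had a row and 14 had a mean of at least 1. For differentiating spermatogonia and meiosis 28 of 30 had a row and 4 such a mean. For post-meiotic germ cells 13 of 18 had a row and 1 such a mean. Markers of other testis cells were also present, with Wt1, a Sertoli cell transcription factor gene, at 53.3 and the mesenchymal filament gene Vim at 491. Of 19 Sertoli and 12 Leydig cell markers, 16 and 8 had a row, and 7 and 4 had a mean of at least 1. The Sertoli cell genes Sox9 and Amh averaged 0.00333 and 0.055 and the steroid synthesis genes Cyp11a1 and Cyp17a1 0.0025 and 0.00333. Of 15 macrophage markers, 9 had a row and 2 reached a mean of at least 1, too few for a test. The mitochondrially encoded list had no member in the table.

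The first principal component held 52.6% of the variance and set the overexpression libraries apart, between 25.75 and 39.19, from the other 9, between -22.87 and -2.16. On the next, with 28.3%, the 5NC libraries lay between 24.45 and 25.95 and all others at or below -0.94. Knockdown replicate 2 lay apart from the other 2 knockdown libraries. Its values also rose with the GC content of the transcripts across genes, relative to the mean library (Spearman's rho 0.55), where the other 2 had -0.17 and -0.02. Replicates of a group correlated at 0.9932 or more across genes, which are not independent of each other.

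**Figure D1:**
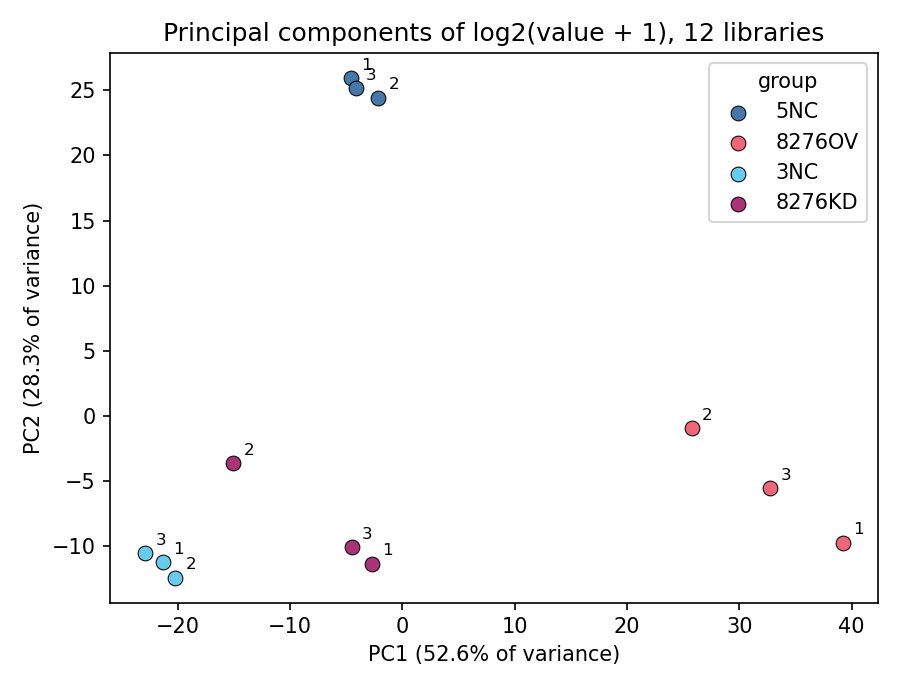
Principal components of log2(value + 1) for the 12 libraries, with group by colour and replicate number beside each point. The overexpression libraries lie to the right, between 25.75 and 39.19, and the 5NC libraries lie at the top, between 24.45 and 25.95.

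The effect of raising lncRNA8276 was read from 8276OV against 5NC. Ugt2a2, a UDP-glucuronosyltransferase gene of the olfactory epithelium, averaged 4.66 ± 0.63 with overexpression and 0.01 ± 0.02 in 5NC, and was listed at 0 in every 3NC and knockdown library. Ccl17, a chemokine that attracts T cells, rose from 7.88 ± 1.88 to 22 ± 3. Aebp1, which codes for a collagen-binding matrix protein, fell from 24.0 ± 0.1 to 2.78 ± 0.22, and the genes for the collagen VI chains Col6a1 and Col6a2 fell from 123 ± 2 to 61.4 ± 5.5 and from 89.6 ± 0.8 to 42.0 ± 4.9. Transcripts for ribosomal proteins and for the respiratory chain rose more often than they fell, and those of the matrix, of the response to hypoxia and of Wnt signalling fell more often, but none of these 5 lists passed with an estimated correlation (adjusted p from 0.38 to 0.55), nor did the Wnt list with a correction for GC content (adjusted p = 0.47).

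Of 11133 genes tested, 8343 changed, 3426 up and 4917 down, and 8692 (78.07%) had libraries that did not overlap between the groups, where chance gives 10%. A change of at least 2-fold was seen in 241 genes, 7 up and 234 down, and this count was 150 without overexpression replicate 1 and 362 without overexpression replicate 2. The change ran with the GC content of the transcript across genes (Spearman's rho -0.79), with a median log2 change of 0.33 in the genes under 44.7% GC and -0.57 in those above 54.5%. Relative to the mean library, rho with GC content was -0.79, -0.61 and -0.74 in the overexpression libraries and 0.44 to 0.53 in 5NC. With each library corrected for GC content and length, 6166 of 10995 genes changed, 4244 of them in the same direction as before, and 53 did so by at least 2-fold.

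**Figure D2:**
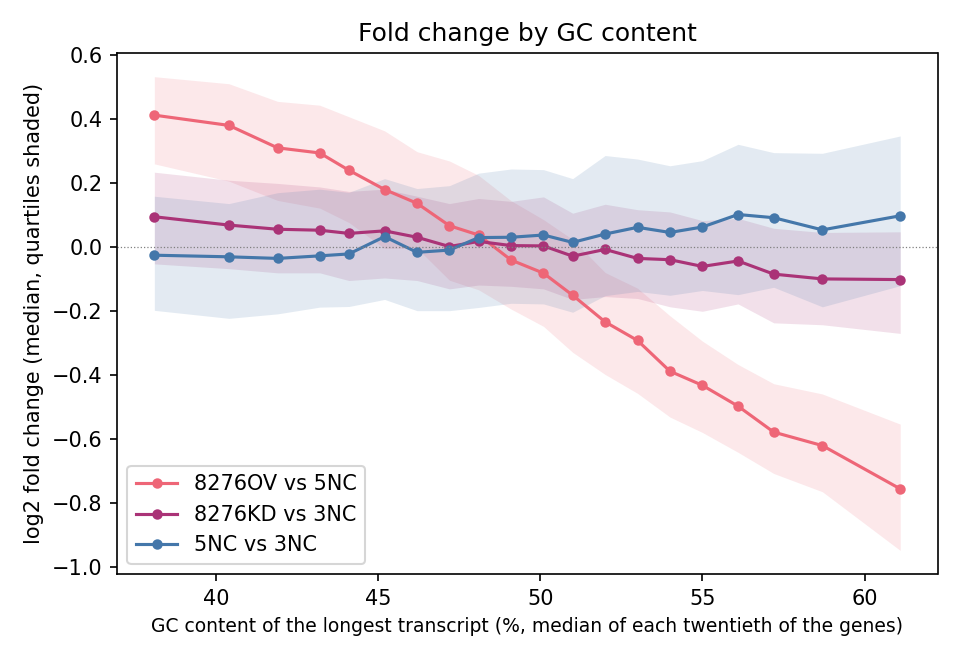
Median log2 fold change (y axis, quartiles shaded) against the GC content of the longest transcript (x axis, percent) in 20 bins of genes for 3 comparisons. For overexpression against 5NC the median goes from 0.41 in the bin lowest in GC to -0.76 in the highest.

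Among the largest rises, Ugt2a2 (gene ID 552899, chromosome 5, from 87459493 to 87482258) had a log2 change of 2.48 (SE 0.086, adjusted p = 9.3e-10). Its locus lies wholly within Ugt2a1, which shares most of its transcript and read 1.5 in overexpression replicate 3 and 0 in all other libraries, so the split of reads between them is uncertain. The predicted gene Gm20594 rose from 215 ± 9 to 659 ± 73 (log2 change 1.61, SE 0.064, adjusted p = 3.8e-09, and 0.94 with the GC correction), Ccl17 by 1.39 (SE 0.15, adjusted p = 3.4e-06) and the vomeronasal receptor gene Vmn2r122 from 0.92 ± 0.23 to 3.21 ± 0.31. The predicted gene Gm3050 rose from 2.73 ± 2.15 to 7.15 ± 2.13 (log2 change 1.33, adjusted p = 0.032), and did not pass without 5NC replicate 3 (0.69), overexpression replicate 1 (1.22) or overexpression replicate 3 (1.21), nor with a pseudocount of 0.1 (1.91) or no filter (1.33, adjusted p = 0.082). Gsta1, a glutathione transferase gene, rose from 19.4 ± 2.0 to 43.4 ± 3.8 (log2 change 1.13, and 0.74 with the GC correction), below its level of 65.5 ± 2.2 in 3NC. Gsta1 is 99.5% identical to Gm3776, 97.2% to Gsta2 and 96.6% to Gm10639 over nearly its whole transcript, so reads of these 4 genes cannot be separated with certainty.

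The largest fall was that of Aebp1 (gene ID 11568, chromosome 11, from 5861866 to 5872248), with a log2 change of -2.73 (SE 0.071, adjusted p = 4e-11). Its level of 2.78 with overexpression compares with 5.03 ± 0.21 in 3NC and 4.72 ± 0.54 in the knockdown. Cd99, a cell surface glycoprotein gene, fell from 9.90 ± 3.14 to 1.09 ± 1.2, and Scand1, for a SCAN domain protein, from 27.9 ± 4.5 to 7.65 ± 3.11. Scand1 lies for 88.4% of its length within Cnbd2. Pgls, of the pentose phosphate pathway, fell from 61.6 ± 5.9 to 19.9 ± 2.6, Chchd10, of the mitochondrial intermembrane space, from 52.1 ± 5.5 to 17.2 ± 4.5, and the predicted gene Gm1673 from 26.0 ± 5.6 to 7.53 ± 0.78. With the GC correction the log2 changes were -2.25 for Aebp1, -1.10 for Pgls, -1.05 for Chchd10, -0.70 for Scand1 and -0.59 for Gm1673, all past the threshold.

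Of the gene lists, 5 passed with the preset correlation and none of these with an estimated one. Counts adjusted over the list alone equalled those over all genes unless given. Of 46 genes for extracellular matrix and integrins, 31 fell and 4 rose (median log2 change -0.43, adjusted p = 0.0021; adjusted p = 0.42 with an estimated correlation). Col6a1 (gene ID 12833, chromosome 10, from 76708792 to 76726044) fell by 0.99 on the log2 scale, and Nid2, for the basement membrane protein nidogen, from 39.9 ± 0.8 to 22.3 ± 1.4 (-0.81), with -0.58 and -0.50 after the GC correction. Col6a1 and Col6a2 stood at 46.0 ± 1.0 and 30.5 ± 1.7 in 3NC, below their overexpression levels. Against 3NC, 19 genes of the list rose and 17 fell (mean difference 0.23, adjusted p = 0.38), and against both controls pooled the list did not pass either (-0.02, adjusted p = 0.57). With the GC correction the list's mean difference from other genes was -0.11 (adjusted p = 0.014; adjusted p = 0.4 with an estimated correlation), where its uncorrected value was -0.26.

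Among 29 genes of hypoxia and glycolysis, 19 fell and 4 rose (median -0.41, adjusted p = 0.03; adjusted p = 0.38 with an estimated correlation). They included Egln1, the oxygen-sensing prolyl hydroxylase, from 27.0 ± 1.6 to 15.2 ± 0.1 (log2 change -0.79, and -0.39 with the GC correction), the angiogenic factor Vegfa, from 53.6 ± 3.8 to 33.0 ± 0.8, and Pdk1, which restrains pyruvate oxidation, from 5.22 ± 0.28 to 2.71 ± 0.18. The log2 change of Vegfa went from -0.68 to -0.59 with the GC correction and that of Pdk1 from -0.75 to -0.90. The list's mean difference was -0.20 before the GC correction and -0.12 after it (adjusted p = 0.023; adjusted p = 0.4 with an estimated correlation). Against 3NC it was -1.08, with 28 down and 0 up. It was -0.64 against both controls pooled. With an estimated correlation adjusted p = 0.014 against 3NC and 0.049 against both pooled. Of 32 Wnt pathway genes, 20 fell and 1 rose (median -0.32, adjusted p = 0.031; adjusted p = 0.38 with an estimated correlation), among them the receptor gene Fzd1, from 7.78 ± 0.20 to 4.22 ± 0.05, the scaffold gene Axin1, from 48.6 ± 0.5 to 32.8 ± 2.0, and the ligand gene Wnt4, from 9.13 ± 0.44 to 3.50 ± 0.88. With the GC correction the Wnt list no longer passed (mean difference -0.04, adjusted p = 0.47), and the log2 changes of Fzd1 and Axin1 went from -0.75 and -0.56 to -0.38 and -0.14. That of Wnt4 went from -1.19 to -0.81, and each of these genes still passed.

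Of 76 cytosolic ribosomal protein genes, 44 rose and 19 fell (median 0.25, adjusted p = 0.00033; adjusted p = 0.55 with an estimated correlation). Rpl38 rose from 2468 ± 133 to 4391 ± 157, Rps27a from 1829 ± 45 to 2914 ± 19 and Rps12 from 1271 ± 36 to 1878 ± 29, each with processed pseudogenes of near-identical sequence that have no row in the table. Log2 changes of Rps27a and Rps12 went from 0.67 and 0.56 to 0.13 and 0.20 with the GC correction, and that of Rpl38 from 0.83 to 1.11. Of 72 nuclear genes of oxidative phosphorylation, 40 rose and 25 fell, or 40 and 27 adjusted over the list alone (median 0.23, adjusted p = 0.0058; adjusted p = 0.42 with an estimated correlation). The rises included Cox7a2, a subunit of cytochrome oxidase, from 148 ± 4 to 233 ± 6, and Uqcrh, a subunit of complex III, from 148 ± 3 to 231 ± 7. The log2 change of Uqcrh was 0.63, against 0.19 with the GC correction and -0.05 against 3NC (adjusted p = 0.29). That of Cox7a2 went from 0.66 to 0.49 with the GC correction. Ndufa4, a further respiratory chain subunit, rose from 502 ± 4 to 780 ± 8, and with the GC correction did not pass (log2 change 0.05, adjusted p = 0.41). The mean difference was 0.15 for the ribosomal and 0.10 for the respiratory list with the GC correction (adjusted p = 0.4 for both with an estimated correlation), and 0.01 and 0.00 with quantile normalization, where neither passed.

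The list for undifferentiated spermatogonia and self-renewal did not pass (adjusted p = 0.76), with 3 of 14 genes up and 8 down. Pou3f1, a GDNF-responsive transcription factor gene, fell from 11.8 ± 0.2 to 6.83 ± 0.49, and Adgra3, an adhesion receptor gene of spermatogonial progenitors, from 12.1 ± 0.2 to 8.65 ± 0.07, while Cd9 rose from 61.7 ± 3.6 to 84.4 ± 2.8. With the GC correction Pou3f1 (-0.12) and Cd9 (0.05) no longer passed, and Adgra3 went from -0.44 to -0.22. The list then had 2 genes up and 4 down. Of 34 cell-cell adhesion genes, 7 rose and 12 fell, or 11 adjusted over the list alone (adjusted p = 0.91). Cdh3, for P-cadherin, fell from 65.8 ± 0.5 to 36.2 ± 2.9 and the nectin gene Nectin2 from 78.1 ± 3.1 to 47.4 ± 5.4, and the gap junction gene Gja1 rose from 16.7 ± 0.2 to 27.3 ± 1.7. The log2 change of Nectin2 went from -0.71 to -0.20 with the GC correction, that of Gja1 from 0.68 to 0.29 and that of Cdh3 from -0.85 to -0.66. Cdh3 and Pou3f1 were lower still in 3NC, at 19.5 ± 0.3 and 3.74 ± 0.47.

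Other lists did not pass by camera with overexpression against 5NC. The members that rose and fell numbered 5 and 13 of 26 for GDNF and FGF to MAPK signalling and targets (adjusted p = 0.69), 22 (24 adjusted over the list alone) and 18 of 50 for cell cycle and DNA replication (0.28), 15 and 9 (8 over the list alone) of 35 for the interferon response (0.23), 8 and 13 of 24 for NF-kB and inflammatory genes (0.76), and 11 and 8 of 24 for sterol synthesis and uptake (0.23). With the GC correction the sterol list passed upward, with 12 genes up and 4 down (mean difference 0.16, adjusted p = 0.0017; adjusted p = 0.061 with an estimated correlation). Against 3NC it passed downward, with 3 up and 19 down (-0.49, adjusted p = 0.0017; adjusted p = 0.035 with an estimated correlation), as did the MAPK list, with 2 up and 22 down (-0.83, adjusted p = 5.7e-06; adjusted p = 0.13 with an estimated correlation). Those that rose and fell against 5NC were 11 and 19 of 40 for the integrated stress and unfolded protein responses (0.76) and 10 and 12 of 26 for p53 targets (0.91). The MAPK list had 10 genes up and 8 down with the GC correction. Its mean difference turned there from -0.10 to 0.13 (adjusted p = 0.069). With that correction the interferon list had 9 up and 9 down and the NF-kB list 2 and 9. The cell cycle list had 14 and 13, the stress response list 10 and 23, and p53 targets 6 and 8. For p53 targets, the median and mean were -0.08 and -0.10 and fry's direction was down, while camera, which compares with other genes, gave up. Of the marker lists, 1 of 7 Sertoli cell genes rose and 3 fell (0.76), 3 of 4 Leydig cell genes fell (0.54), 3 of 15 peritubular and fibroblast genes rose and 8 fell (0.74), 1 of 4 histone genes fell (0.76), and of 4 genes of differentiating spermatogonia and meiosis 1 rose and 1 fell, or 0 adjusted over the list alone (0.76).

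Lowering lncRNA8276 was examined in 8276KD against 3NC. Genes of hypoxia and glycolysis fell almost throughout, among them Bnip3, which acts in mitophagy, from 114 ± 4 to 49.2 ± 4.5, and the lactate dehydrogenase gene Ldha, from 978 ± 16 to 644 ± 23. Of 26 genes of MAPK signalling and its targets 16 fell (adjusted p = 0.057 for the list with an estimated correlation), among them the transcription factor genes Egr1, from 46.8 ± 1.3 to 13.5 ± 0.7, Etv4, from 31.3 ± 1.0 to 16.1 ± 1.1, and Fosl1, from 31 ± 1 to 8.37 ± 1.21. The glutathione transferase genes Gsta1 and Gsta4 fell from 65.5 ± 2.2 to 9.61 ± 1.38 and from 697 ± 13 to 189 ± 6. Dcn, for the matrix proteoglycan decorin, rose from 21.6 ± 0.7 to 52.8 ± 2.4. The 3NC libraries stood apart in several of these genes, with Bnip3 at 21.3 ± 0.8, Ldha at 405 ± 12, Etv4 at 3.59 ± 0.17 and Fosl1 at 1.72 ± 0.22 in 5NC.

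In all, 4397 of 11133 genes changed, 2236 up and 2161 down, and 91 did so by at least 2-fold, 28 up and 63 down. Libraries did not overlap in 5529 genes (49.66%, against 10% by chance). Without knockdown replicate 2, which stood apart, 4952 genes changed. Of the 4397 genes, 1928 (43.8%) changed in the same direction against 5NC, 984 up and 944 down, and 844 passed in the opposite direction, in comparisons that share the knockdown libraries. Over all genes the sign was the same in 60.6%, where simulations of unchanged groups that share 3NC gave 66.6%. The controls differed from each other, unlike those groups, so the simulated share sets no bound. The fold change had a weaker relation to GC content than with overexpression (Spearman's rho across genes -0.23).

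Stmn4, for a microtubule-binding stathmin, rose from 0.54 ± 0.14 to 3.09 ± 0.32, with 0.36 ± 0.05 in 5NC, and the membrane-spanning gene Ms4a4d from 2.90 ± 0.26 to 8.09 ± 0.44, with 1.28 ± 0.16 in 5NC. Ccdc68 (gene ID 381175, chromosome 18, from 69924858 to 69969488), a centriole component, rose from 3.58 ± 0.15 to 12.6 ± 1.5 (log2 change 1.57, SE 0.078, adjusted p = 1.1e-08), with 5.19 ± 0.30 in 5NC. Rsc1a1, a regulator of glucose transport, rose from 0.07 ± 0.12 to 3.40 ± 1.24, but its locus lies wholly within Ddi2, so the source of its reads is uncertain. Ptprz1, a receptor tyrosine phosphatase gene, rose from 3.59 ± 0.07 to 10.8 ± 1.3, and Dcn (gene ID 13179, chromosome 10, from 97479500 to 97518163) had a log2 change of 1.25 (SE 0.049, adjusted p = 1.3e-09). Both lay higher in 5NC, Ptprz1 at 19.2 ± 0.5 and Dcn at 112 ± 3.

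Gsta4 (gene ID 14860, chromosome 9, from 78191966 to 78209349) fell by 1.88 on the log2 scale (SE 0.041, adjusted p = 3.2e-12) and stood at 350 ± 13 in 5NC, above the knockdown. Spp1, for the secreted phosphoprotein osteopontin, fell from 182 ± 8 to 50.04 ± 2.57, a level near the 50.4 ± 2.0 of 5NC, and Sprr1a, a gene of the cornified envelope, from 4.88 ± 0.82 to 0.49 ± 0.47, with 0.17 ± 0.06 in 5NC, against which the knockdown did not pass (log2 change 0.30, adjusted p = 0.17). Egr1 (gene ID 13653, chromosome 18, from 34861207 to 34864956) fell by 1.72 (SE 0.051, adjusted p = 7.1e-11), also below its 21.4 ± 0.5 in 5NC. Fosl1 fell by 1.78 (SE 0.13, adjusted p = 3.1e-07), and 33.7% of its length overlaps Ccdc85b. Gsta1 fell by 2.65 (SE 0.092, adjusted p = 4.3e-10), with the uncertainty from its 3 similar genes given above.

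**Figure D3:**
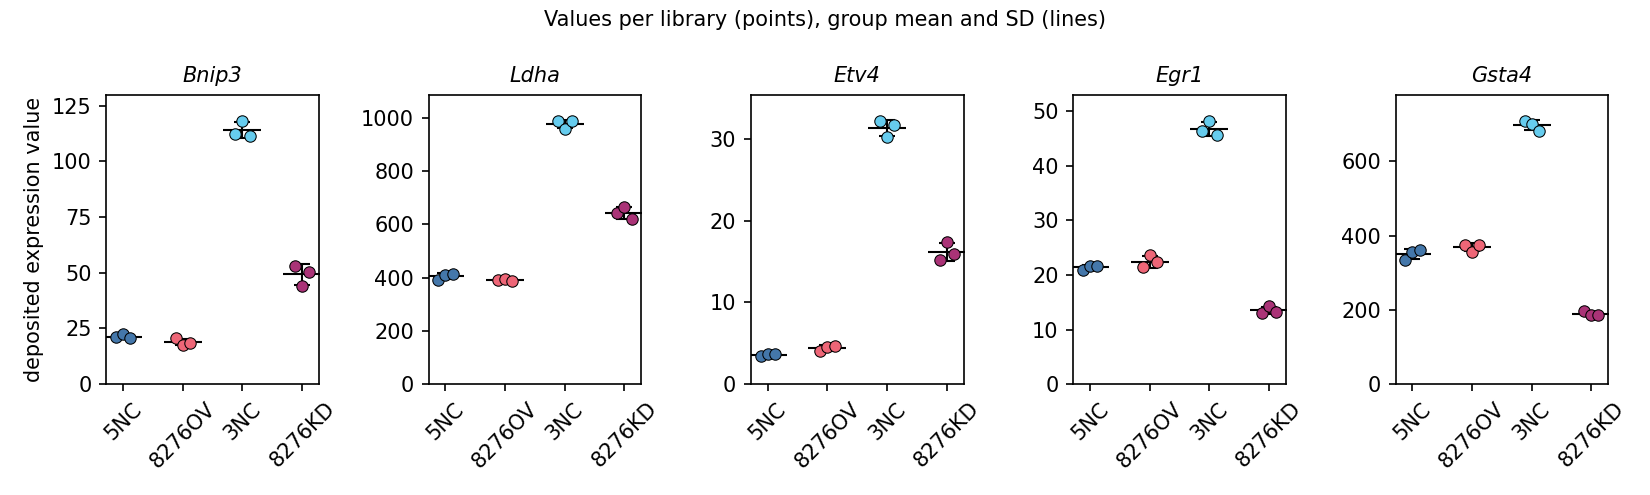
Deposited expression values (y axis, length- and depth-scaled) of 5 genes per library (points) in the 4 groups, with group mean and SD (lines). Bnip3, Ldha and Etv4 are highest in 3NC, lower in the knockdown and lowest in 5NC and overexpression, whereas Egr1 and Gsta4 are lowest in the knockdown, at 13.5 and 189.

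Of 29 hypoxia and glycolysis genes, 27 fell and 1 rose (median log2 change -0.47, adjusted p = 4.4e-17; adjusted p = 0.0046 with an estimated correlation). Bnip3 (gene ID 12176, chromosome 7, from 138890836 to 138909506) fell by 1.2 on the log2 scale, and Ndrg1, a stress-responsive gene, from 68.7 ± 1.2 to 37.5 ± 1.7. Bnip3 and Ldha have pseudogenes of near-identical sequence without a row in the table. In 26 of the 29 genes all 3NC libraries lay above all 9 others, which held for 11.1% of all genes. Against 5NC in place of 3NC the list turned upward, with a mean difference of 0.35 and 19 genes up and 4 down (adjusted p = 2.8e-05; adjusted p = 0.11 with an estimated correlation).

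The list for GDNF and FGF to MAPK signalling and targets had 16 of 26 genes down and 1 up (median -0.38, adjusted p = 2e-07; adjusted p = 0.057 with an estimated correlation, and adjusted p = 0.0087 with that and the GC correction). Of 24 genes for sterol synthesis and uptake, 13 fell, or 14 adjusted over the list alone, and 2 rose (median -0.19, adjusted p = 0.00059; adjusted p = 0.019 with an estimated correlation). They included the squalene synthase gene Fdft1, from 15.2 ± 0.2 to 11.6 ± 0.3, and the lanosterol synthase gene Lss, from 8.79 ± 0.94 to 5.51 ± 0.52, neither of which passed against 5NC (log2 changes 0.02 and -0.14). Among 26 p53 targets 13 fell, or 15 adjusted over the list alone, and 3 rose (median -0.19, adjusted p = 0.00059; adjusted p = 0.019 with an estimated correlation). The pro-apoptotic Pmaip1 fell from 4.63 ± 0.18 to 1.99 ± 0.18, the kinase gene Plk3 from 8.12 ± 0.34 to 4.28 ± 0.60 (log2 change -0.17 against 5NC, adjusted p = 0.13), and Dcxr, a sugar reductase gene, from 10.4 ± 0.3 to 5.44 ± 0.13. Of 76 ribosomal protein genes, 34 fell and 7 rose, or 38 and 8 adjusted over the list alone (median -0.11, adjusted p = 0.00059; adjusted p = 0.67 with an estimated correlation, and adjusted p = 0.31 with quantile normalization). Rps19 fell from 1050 ± 3 to 825 ± 19, Rpl14 from 1163 ± 10 to 946 ± 47 and Rpl36 from 892 ± 28 to 593 ± 35, all with near-identical pseudogenes. Against 5NC the sterol list passed upward (mean difference 0.46, adjusted p = 2.4e-05; adjusted p = 0.015 with an estimated correlation), as did the ribosomal list (0.10, adjusted p = 0.0052; adjusted p = 0.52 with an estimated correlation). The MAPK and p53 lists had positive mean differences there, of 0.27 and 0.07, and did not pass (adjusted p = 0.099 and 0.33).

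**Figure D4:**
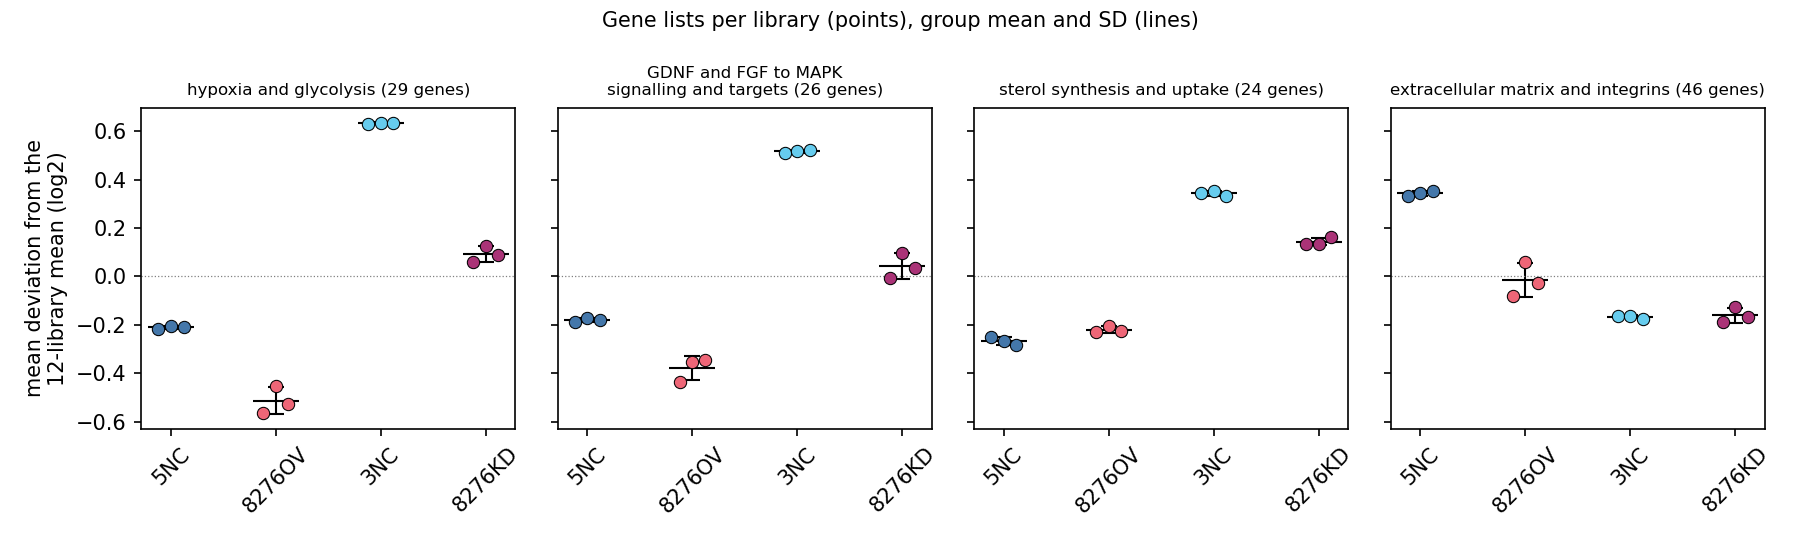
Mean log2 deviation of each library from the 12-library mean (y axis) over the members of 4 gene lists, by group, with points for libraries and lines for the group mean and SD. For hypoxia and glycolysis the group means are 0.63 in 3NC, 0.09 in the knockdown, -0.21 in 5NC and -0.51 with overexpression.

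In the spermatogonial list, which did not pass with the knockdown (adjusted p = 0.67), 5 of 14 genes rose and 5 fell. Pou3f1 rose from 3.74 ± 0.47 to 9.76 ± 1.07 and Uchl1 from 77.1 ± 4.6 to 125 ± 12, and Etv5, a transcription factor gene of stem cell self-renewal, fell from 7.81 ± 0.09 to 4.09 ± 0.44. In 5NC Pou3f1 stood at 11.8 and Etv5 at 3.10 ± 0.41, on the other side of the knockdown. Of 34 adhesion genes 13 rose and 9 fell (adjusted p = 0.47), with the desmosome gene Dsp rising from 1.41 ± 0.20 to 3.96 ± 0.35 and the neural adhesion gene Ncam1 falling from 11 ± 0.3 to 7.45 ± 0.43.

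No other list passed by camera with the knockdown against 3NC. Those that rose and fell were 15 and 14 of 46 matrix genes, or 17 and 17 adjusted over the list alone (adjusted p = 0.85), 13 and 15 (16 over the list alone) of 50 cell cycle genes (0.53), 10 and 3 of 32 Wnt genes (0.47), 4 and 11 of 35 interferon genes (0.47), 5 and 6 of 24 NF-kB and inflammatory genes (0.67), 13 and 14 (15 over the list alone) of 40 stress response genes (0.67) and 19 and 6 of 72 respiratory genes, or 15 and 6 over the list alone (0.47). After the GC correction 14 respiratory genes rose and 15 fell (mean difference 0.01, adjusted p = 0.97). Against 5NC, 31 matrix genes fell and 4 rose (mean difference -0.47, adjusted p = 8.3e-08; adjusted p = 0.15 with an estimated correlation), and against both controls pooled 26 fell and 4 rose (-0.22, adjusted p = 7.9e-06; adjusted p = 0.38 with an estimated correlation). The respiratory list passed upward against 5NC (0.12, adjusted p = 0.0056; adjusted p = 0.37 with an estimated correlation) and against both pooled (0.08, adjusted p = 0.039; adjusted p = 0.5 with an estimated correlation). Sertoli cell markers had 4 of 7 up and 2 down (0.47), and differentiating spermatogonia and meiosis 2 of 4 down, with 1 up as well over the list alone (0.47). None of 4 histone genes passed (0.85). Of 15 peritubular and fibroblast markers 3 rose, or 4 over the list alone, and 6 fell (0.82), with a median of -0.15 but a mean of 0.01 and fry's direction up where camera's was down. The 4 Leydig cell markers had 1 up and 1 down (0.85), with a median of -0.06, a mean of -0.03 and fry's direction up.

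The difference between the controls was measured as 5NC against 3NC. Hypoxia and glycolysis genes were lower in 5NC, as were sterol genes. Of MAPK genes 16 of 26 were lower, and of matrix genes 29 of 46 higher, which did not pass as lists with an estimated correlation (adjusted p = 0.087 and 0.23). The MAPK list passed with both an estimated correlation and the GC correction (adjusted p = 0.0069). Etv4 was 3.59 ± 0.17 in 5NC and 31.3 ± 1.0 in 3NC. Dcn stood at 112 ± 3 and 21.6 ± 0.7, Aebp1 at 24.0 ± 0.1 and 5.03 ± 0.21, and Upk3b, a uroplakin gene, at 792 ± 11 and 240 ± 6.

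Between the controls 6304 genes differed, 3419 higher and 2885 lower in 5NC, 297 of them by at least 2-fold. Libraries did not overlap in 7761 genes (69.71%, against 10% by chance). Of the lists, 27 of 29 hypoxia and glycolysis genes were lower (adjusted p = 4.2e-17; adjusted p = 0.0023 with an estimated correlation), 19 of 24 sterol genes, or 20 adjusted over the list alone, with 2 higher (4e-09; adjusted p = 0.0023 with an estimated correlation), and 17 of 26 p53 targets, with 5 higher (0.0023; adjusted p = 0.034 with an estimated correlation). MAPK genes had 16 of 26 lower, or 17 over the list alone, and 3 higher (1.5e-06; adjusted p = 0.087 with an estimated correlation). Of 46 matrix genes 29 were higher and 9 lower (7.4e-06; adjusted p = 0.23 with an estimated correlation). Of 76 ribosomal protein genes 50 were lower and 2 higher (6.8e-09; adjusted p = 0.24 with an estimated correlation, and adjusted p = 0.41 with quantile normalization), and of 72 respiratory genes 26 were lower and 5 higher, or 4 over the list alone (0.031; adjusted p = 0.36 with an estimated correlation). The respiratory list no longer passed without 5NC replicate 2 (mean difference -0.08) or 3NC replicate 3 (-0.08), with quantile normalization (adjusted p = 0.15), without a mean-variance trend (-0.09, adjusted p = 0.05) or with the GC correction (-0.07, adjusted p = 0.18), where its value with all libraries was -0.09. No other list passed by camera between the controls, with adjusted p from 0.075 to 0.77.

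The treatments were then compared with each other, as opposite interventions on the same RNA. Gsta1 rose with overexpression and fell with knockdown, a difference in log2 change of 3.78 (SE 0.13, adjusted p = 5.5e-10). Upk3b, the germline piRNA pathway gene Piwil2, the BMP antagonist gene Nbl1, Pou3f1 and the testis dipeptidase gene Dpep3 fell with overexpression and rose with knockdown. Piwil2 went from 5.39 ± 0.29 to 2.84 ± 0.07 and from 1.41 ± 0.16 to 3.01 ± 0.49, Nbl1 from 15.9 ± 0.5 to 7.09 ± 1.34 and from 4.67 ± 0.18 to 8.97 ± 1.53, Upk3b from 792 to 493 ± 40 and from 240 to 387 ± 23, and Dpep3 from 1.35 ± 0.21 to 0.44 ± 0.03 and from 0.91 ± 0.12 to 2.09 ± 0.21. Of these, both treated groups lay between the 2 controls for Upk3b, Piwil2, Nbl1 and Pou3f1. After the GC correction the log2 changes with overexpression went from -1.08 to -0.37 for Nbl1, from -0.70 to -0.32 for Dpep3 and from -0.68 to -0.38 for Upk3b. That of Piwil2 went from -0.73 to -0.74. The log2 change of Pou3f1 went from -0.71 to -0.12 and no longer passed (adjusted p = 0.096).

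The change differed between the treatments in 6799 genes, being higher with overexpression in 2756 and lower in 4043. This difference ran with GC content as well (Spearman's rho across genes -0.67), with a median of 0.27 in the genes under 44.7% GC and -0.49 in those above 54.5%. In all, 5495 genes differed with the GC correction, 3874 of them in the same direction as before. Of genes called in both, 979 (29.9%) moved in opposite directions and 2295 in the same direction. Of the latter, 1061 rose in both, where 688 would if the calls were independent, and 1234 fell in both, where 954 would. Opposite moves were fewer than independent calls would give. Here 373 rose with overexpression and fell with knockdown, against 665, and 606 fell and rose, against 988. Across genes the fold changes correlated at 0.26 (Pearson) and 0.29 (Spearman), and genes are not independent replicates. Both fold changes also fell with GC content across genes (Spearman's rho -0.79 and -0.23). The differences between replicates 1 and 2 of the 2 treated groups correlated with each other at a rho of 0.68. The overlap was not counted with the GC correction, so a shared relation to GC content was not separated from a shared response.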

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

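The contrast of the 2 effects, its list tests and the counts over other splits of the libraries were planned, and the tests of the 3 patterns weighed here were chosen only after the results were seen. Groups of 3 libraries are too small for a search for single deviating samples.

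A difference between the treatments was found in 6799 genes, by the test of the difference between the overexpression and knockdown effects, and it ran with GC content across genes (Spearman's rho -0.67). The same test on lists gave mean differences from other genes of 0.33 for hypoxia and glycolysis (15 of 29 genes higher with overexpression, 5 lower; adjusted p = 0.0041, and adjusted p = 0.16 with an estimated correlation), 0.31 for ribosomal proteins (48 of 76 higher, 11 lower; 1.5e-08 and adjusted p = 0.27), 0.34 for sterol synthesis and uptake (15 of 24 higher, 2 lower; 0.0018 and adjusted p = 0.072) and 0.37 for GDNF and FGF to MAPK genes (13 of 26 higher, 5 lower; 0.013 and adjusted p = 0.3). It was -0.27 for matrix genes (30 of 46 lower, 6 higher; 0.0016 and adjusted p = 0.3), -0.30 for the Wnt pathway (20 of 32 lower, 2 higher; 0.0041 and adjusted p = 0.13), 0.14 for respiratory genes (36 of 72 higher, 16 lower; 0.0055 and adjusted p = 0.33) and 0.21 for the interferon response (10 of 35 higher, 5 lower; 0.031 and adjusted p = 0.16). Adjusted over the list alone, 50 ribosomal genes were higher and 21 Wnt genes lower, and the other counts were equal. The interferon list did not pass without knockdown replicate 1 (0.20) or with a mean of at least 5 (0.23), the ribosomal and respiratory lists with quantile normalization (0.06 and 0.03), or the Wnt list with the GC correction (-0.15, adjusted p = 0.054).

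Of 100 drawn splits of the libraries within each pair of groups, 2 gave as many genes as the real 6799, the real one included. Most splits mix treated and control libraries, which removes the effect of each treatment as well as any difference between the effects. The count therefore cannot decide whether chance gave the difference. The highest other split gave 7915 genes. It exchanges all overexpression and 5NC libraries, so that it tests the sum of the 2 effects in place of their difference, and points to the structure of the groups. Within each pair of groups there are 10 splits, too few for a share under 0.05. Only the real split, 1 of the 10, gave as many genes as were reported, 8343 for overexpression against 0 in the highest other, 4397 for knockdown against 1, and 6304 between the controls against 0.

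The first pattern is that the knockdown changes run with the difference between the controls, and 3NC is part of both. The correlation of the fold changes, 0.5, and the share with the same sign, 62.7%, were no higher than a shared control alone gives, with means of 0.5 and 66.6% in 100 simulations of unchanged groups from the spread between replicates. Noise between the 3NC libraries is argued against as the whole source by the size of the shared change, a covariance of 0.0543 where the simulations reached 0.00489 at most. Any lasting difference of 3NC from the other groups gives such a covariance, so it adds nothing beyond the calls already made in both comparisons. A fall with the knockdown that either control would show is argued against for hypoxia and glycolysis genes as a set, which against 5NC had a mean difference of 0.346, with 19 of 29 up and 4 down (adjusted p = 2.8e-05, and adjusted p = 0.11 with an estimated correlation). The 3NC libraries lay above all others in 26 of the 29 genes, but this nearly restates the falls for which the list was singled out, so a state of the 3NC cells, from vector, culture or day of harvest, and an effect of the knockdown cannot be told apart here.

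The second pattern is the relation of the overexpression changes to GC content. A GC-dependent bias that varies between libraries is consistent with the difference between knockdown replicates 1 and 2, which share no library with the overexpression comparison and correlated with its fold changes across genes at a rho of 0.65. After the correction for GC content and length, 4244 of 8251 calls with a GC value kept their direction and passed. Another 499 passed in the opposite direction, and 1423 genes were newly called. The correction left the overall level of each library in place, with a median log2 change of -0.091 and 26.4% rises among the calls. An overall shift, or a bias that the correction missed, could keep calls, so GC content and length as their whole cause cannot be decided. The overexpression libraries averaged 93.8% of the depth of the deepest. A difference in depth is argued against for replicates 1 and 2, at 95.1% and 97.8%, within the 89.5% to 100% of the other 9. Replicate 3, at 88.5%, lay below this range, so depth is not argued against for that library. An effect of lncRNA8276 on GC-rich transcripts stays open and was not tested, because the overexpression libraries, with a rho of -0.79 to -0.61, all lay below the lowest other library, at -0.17.

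The third pattern is the presence of Ugt2a2 in the overexpression libraries, at a mean of 4.66, with 0.03 in 5NC replicate 3 and 0 in all other libraries. Activation of the surrounding region of chromosome 5 to a similar level is argued against by 7 other measured genes within 500000 bases, of which the highest mean with overexpression was 0.063, in Csn3, which averaged 0.45 in 3NC. Ugt2a1, which overlaps Ugt2a2 and read 1.5 in overexpression replicate 3, was left out of this test. Reads of the introduced RNA assigned to Ugt2a2 and induction of the gene itself by the overexpression cannot be told apart here, since the sequence of lncRNA8276 was not used here.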

How the results depend on the processing

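The GC correction was chosen only after the data were seen, and the other alternatives were planned. No count of changed genes moved by over 1.5 times except with the demand for a 2-fold change as well, which left 241, 91, 297 and 357 genes for overexpression, knockdown, the controls and the difference between the effects. With a replicate left out the counts were 7709 to 8381, 3371 to 4952, 5481 to 5607 and 6209 to 7112, and with a replicate block 8305, 4364, 6256 and 6745. The 2-fold counts moved by over 1.5 times with a pseudocount of 0.1, to 457, 182, 469 and 612, with a mean of at least 5, to 56 for knockdown, with the GC correction, to 53 for overexpression and 136 for the difference between the effects, against the other control, to 560 for overexpression and 170 for knockdown, and against both pooled, to 34 for knockdown. They also did so without overexpression replicate 1, at 150, and replicate 2, at 362. Over all alternatives, named genes kept their direction and side of the threshold 1125 times, reversed 31 times and no longer passed 17 times (5 for Gm3050, 2 for Cd9, 2 for Piwil2 and 1 each for Ndufa4, Pou3f1, Dcn, Spp1, Bnip3, Plk3, Lss and Nbl1), and lists kept both 1252 times, reversed 8 times, no longer passed 25 times and newly passed 14 times.

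Of the overexpression calls, 41.1% were rises, and 50% with median-of-ratios rescaling, 52.6% with quantile normalization and 26.4% with the GC correction. Quantile normalization moved the median log2 change of all genes from -0.09 to 0.03 and left 2 lists called for overexpression in place of 5. Against the other control 3 lists were called. For the knockdown 2 were called with the pooled controls. Over the alternatives the adjusted p of the lists that passed with overexpression ranged from 0.00018 to 0.57 for matrix, 2e-12 to 0.044 for hypoxia, 0.022 to 0.6 for Wnt, 5.9e-05 to 0.67 for ribosomal and 0.0015 to 0.7 for respiratory genes, and for the sterol and MAPK lists from 0.0017 to 0.33 and from 5.7e-06 to 0.76. With knockdown they were 1.7e-18 to 0.18 for hypoxia, 1.7e-10 to 0.35 for MAPK, 2.4e-05 to 0.14 for sterol, 8.7e-05 to 0.61 for p53 and 1.2e-05 to 0.91 for ribosomal genes, and for the matrix and respiratory lists 8.3e-08 to 0.98 and 0.0056 to 0.97. Between the controls they were 4.1e-10 to 0.41 for ribosomal and 0.0099 to 0.18 for respiratory genes, and for the difference between the effects 1.6e-10 to 0.13, 0.0014 to 0.29, 0.0022 to 0.054 for Wnt and 0.023 to 0.082 for interferon genes. The ribosomal and respiratory lists for overexpression were lost with quantile normalization and against the other control, and the Wnt list with these, a mean of at least 5, the pooled controls and the GC correction.

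Against the other control 8410 genes changed with overexpression, 6110 of them shared with the main comparison, and 6178 with knockdown, 1928 shared. Values that reversed there, log2 changes for genes and mean differences for lists, were for overexpression 0.225 for matrix genes, -0.584 for Gsta1, 0.405 for Col6a1, 0.446 for Col6a2, -0.045 for Uqcrh, -0.269 for Cd9, 0.728 for Pou3f1, 0.852 for Cdh3, 0.5 for Nbl1, 0.674 for Piwil2 and 1.035 for Upk3b. With the pooled controls they were 0.009 for Pou3f1, 0.002 for Cdh3 and 0.175 for Upk3b. For knockdown they were 0.267 for MAPK genes, 0.073 for p53 targets, 0.455 for sterol genes, 0.346 for hypoxia genes, 0.105 for ribosomal proteins, -0.786 for Ptprz1, -1.070 for Dcn, 0.3 for Sprr1a, 1.779 for Fosl1, -0.255 for Pou3f1, 0.314 for Etv5, 1.901 for Etv4, 1.165 for Bnip3, 0.666 for Ldha, 0.022 for Fdft1, 0.088 for Rps19, -0.771 for Nbl1, -0.679 for Piwil2 and -1.033 for Upk3b. With the pooled controls they were 0.132 for sterol genes, -0.001 for ribosomal proteins, where camera gave the other direction, 0.001 for Fosl1, 0.492 for Etv4, 0.031 for Ldha and -0.173 for Upk3b. These reversals came with a change of the libraries that serve as control. The cause of the other changes was not tested. At the estimated depth, genes with a mean under 1 were not tested, and changes under 1.2-fold were mostly missed in simulated data. Far fewer genes changed in those data than were called here, which made the adjusted threshold stricter, so this limit does not carry over directly.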

Other observations

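The genes of this part were chosen after their values were seen, from the 8 genes in each direction whose smaller change against the 2 controls was largest, and no test was added. Some knockdown changes held against either control. The fold changes of all genes against the 2 controls had the same sign in 60.6%, or 57.4% with the GC correction. Simulated unchanged groups that share 3NC gave 66.6%. The 2 controls differed in 6304 genes, unlike those groups, so this share cannot decide whether the agreement exceeds that from a shared group. The alkaline phosphatase gene Alpl averaged 1.40 ± 0.30 in the knockdown, 5.03 ± 0.82 in 3NC and 5.19 ± 0.44 in 5NC, and the xanthine dehydrogenase gene Xdh 2.48 ± 0.41, 8.08 ± 0.63 and 7.65 ± 0.21. Serpinf1, for a secreted inhibitor of angiogenesis, stood at 19.6 ± 1.2, 51.0 ± 0.1 and 41.5 ± 2.0, and the Hedgehog co-receptor gene Boc at 0.36 ± 0.01, 1.95 ± 0.17 and 1.98 ± 0.07. Cdkn3, a phosphatase gene of the cell cycle, was higher, at 43.9 ± 1.4, 24.6 ± 1.5 and 23.1 ± 0.7. With overexpression these genes stood near the knockdown, Alpl at 1.52 ± 0.24, Xdh at 3.76 ± 0.25, Serpinf1 at 18.7 ± 1.5, Boc at 0.68 ± 0.10 and Cdkn3 at 39.9 ± 4.1.

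Of the genes that changed with overexpression, 6110 (73.2%) kept their direction against 3NC, and 3460 of 6166 (56.1%) did with the GC correction. The 2 comparisons share the overexpression libraries, and the fold changes of all genes had the same sign in 79.4%, or 65.1% with the GC correction. Simulated unchanged groups that share 3NC gave 66.6% on average and 67.7% at most. The 2 controls differed in 6304 genes, unlike those groups, so the simulation sets no bound for either share. Whether the corrected counts go beyond what a shared group gives was therefore not settled. The uncorrected ones are mixed with the relation to GC content as well. Serpinb9b, a protease inhibitor gene, averaged 150 ± 1 with overexpression, 71.1 ± 0.6 in 5NC and 54.6 ± 2.6 in 3NC, and the calcium-binding S100a4 gene 589 ± 35, 314 ± 8 and 294 ± 11. Macrod1, an ADP-ribose hydrolase gene, stood at 0.76 ± 0.16, 3.71 ± 0.43 and 3.29 ± 0.48, and Ino80b, of a chromatin remodelling complex, at 4.13 ± 0.50, 11.5 ± 0.6 and 11.7 ± 0.1. Among hypoxia and glycolysis genes, 19 of 29 fell with overexpression against both controls and none rose, and 4 fell and 1 rose with the knockdown against both. Over all 11133 genes, 3623 fell and 2487 rose with overexpression against both, and 944 and 984 with the knockdown. Against 5NC alone, 19 of the 29 fell and 4 rose with overexpression. In 26 of them all 3NC libraries lay above all others, so falls against 3NC add little. These counts are without the GC correction. The integrated stress and unfolded protein response list had 11 of 40 genes up and 14 down with the knockdown against both controls.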
